A study of Mus musculus with 6 samples.

How the data were processed

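Total RNA of both ventricles from mouse embryos was sequenced as 3 control and 3 knockout libraries. Per the labels' protocols, ribosomal RNA was depleted and libraries were made with a stranded total RNA kit, although the labels also name an mRNA kit of the same maker, and 50 bp single-end reads were taken on an Illumina HiSeq. Per the submitters' processing notes, TopHat2 2.0, Partek 6.6, DESeq and the mm10 genome were used. The role of each tool and whether counting used strand are not given in the sources used here, so reads of overlapping and antisense genes cannot be told apart. Groups came from the sample labels. The labels say that 2 hearts were pooled per replicate.

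The deposited table held estimated counts per transcript for each library, which need not be whole: 51.0% to 53.2% of the estimated counts of a library were off a whole number by over 1e-06. It also held RPKM values, which the authors scaled by transcript length and library total, and a fold and p-values of the authors' own comparison. RPKM recomputed from the counts was within 0.1% for 100% of values above 0.01 in each library. The authors' fold (a ratio) and p-value columns are printed only where the authors' deposited table is named; 2870 fold cells hold spreadsheet errors and were not used. That table lists 3382 transcripts at FDR under 0.05, of which 1605 are higher and 1768 lower. By the deposited read numbers, 95.2% to 98.6% of the sequenced reads of a library were mapped. Gene positions are those of the deposited table, in mm10, with the end set 1 base lower than written because it was 1 above the annotated end.

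Counts were summed over the 30031 transcripts to 19251 gene symbols and rounded to whole numbers. Before rounding, 94.5% of sums were within 0.01 of a whole number. Symbols changed to dates by a spreadsheet, 58 transcripts in all, were restored from their accessions. No transcript of the mitochondrial chromosome was in the table. Gene totals were 12807218 to 32663845 counts per library, so that 3 counts, the floor for a count of 0, stand for 0.0918 to 0.234 CPM per library. Floors cover counting error only, since PCR reads without molecular identifiers are not independent molecules. Chi-square per degree of freedom between replicates ran from 2.94 to 10.7, so no 2 libraries differed by sampling noise alone.

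The test was edgeR 4.0.16 (quasi-likelihood, TMM scaling, filterByExpr with a minimum count of 10 and total of 15) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over 14292 genes and a threshold of 0.05. CPM values are TMM-scaled, except that the summed level of Y-linked genes and the level of Xist per library are relative to the raw library total. Common biological variation was 5.58%. Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2, adjusted over 31 lists, with an estimated correlation and fry as alternatives. A list of mitochondrially encoded proteins had 0 members in the table. Tests on one value used exact permutation in SciPy 1.17.1, whose smallest two-sided p for 3 against 3 is 0.1. Sequences were compared with blastn 2.17.0. On simulated counts of 14292 genes for this comparison, 44.9% of genes changed by the smallest fold tried, 80.0% of those changed 1.5-fold, 92.0% of those changed 2-fold and 96.0% of those changed 4-fold were recovered, with 9 false calls among 165. Only 49 or 50 genes were changed at each fold, far fewer than the 6349 called in the data. The adjustment was therefore stricter in the simulation, and its shares do not carry over to the data.

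The groups, tests, lists and rule for named genes were fixed before the data were examined. The rule takes Esrra, Esrrg, Esrrb and Nkx2-5, the 10 greatest rises and 10 greatest falls among changed genes with a mean of at least 50 counts whose groups do not overlap, and per list up to 4 changed members of the majority direction and up to 2 of the other by adjusted p, or the 2 highest where none changed; the text names fewer in order of adjusted p, and 2 genes that the rule takes are not reported here. Groups did not overlap in 53.7% of genes, where chance gives 10%. Alternatives were other scalings and filters, DESeq2 1.42.0, limma-voom, robust dispersion, transcripts in place of genes, a replicate block, removal of GC and length trends (a GC value was found for 98.6% of genes), leaving out each library, and 3 chosen after seeing the data, which were a Y-linked covariate, thinning to 12807218 counts and leaving out the libraries of 1 sex.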

Results

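RNA was measured by sequencing in heart ventricles of mouse embryos at embryonic day 17.5. The libraries labelled knockout came from embryos in which Cre recombinase, driven by the Nkx2-5 promoter that is active in cardiac progenitors, was combined with floxed alleles of Esrra and Esrrg. These genes encode the estrogen-related receptors alpha and gamma, orphan nuclear receptors known as regulators of mitochondrial energy metabolism. The control libraries came from Cre-negative embryos with floxed alleles. Each group had 3 libraries, and each library pooled 2 hearts. Libraries had 39621555 to 86895519 sequenced reads, and 12807218 to 32663845 estimated counts over annotated genes. The deepest was knockout replicate 1. A total of 14292 genes was tested. On log2 counts-per-million (CPM) values the first principal component held 72.6% of the variance and parted the groups, with controls from -32.3 to -26.8 and labelled knockouts from 27.7 to 32.2. Pearson correlations across genes, which are not independent replicates, were 0.992 to 0.995 within groups and 0.970 to 0.976 between them.

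The first comparison was that of the targeted genes, which checks the labels. Esrra fell from 75.8 ± 6.56 to 42.9 ± 1.63 CPM (SD, n = 3 per group) and was lower in 3 of 3 labelled knockout libraries. Esrrg went the other way: it rose from 81.7 ± 2.07 to 115.6 ± 5.29 CPM and was higher in 3 of 3 labelled knockout libraries. The log2 fold change was -0.83 (SE 0.0638) for Esrra, with an adjusted p of 3.66e-07, and 0.50 (SE 0.0465) for Esrrg, with an adjusted p of 2.22e-06, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Esrra lies on chromosome 19 at 6910977 to 6921808 and Esrrg on chromosome 1 at 187609006 to 188214884 of mm10. The counts cover whole annotated transcripts, including exons outside the deleted part, so they do not measure the loss of the floxed exons or of protein. Because Esrrg went against its label, every direction below is that of the libraries labelled knockout against the control libraries.

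The estimated counts of the Esrrg transcripts did not move together. Reads that match both transcripts are shared out by estimation, and the test takes no account of that uncertainty. The isoform NM_011935 rose, with a log2 fold change of 1.01 (SE 0.103) and an adjusted p of 0.000569. The isoform NM_001243792 fell, with a log2 fold change of -0.46 (SE 0.0892) and an adjusted p of 0.0102, both by edgeR on transcripts. The authors' deposited table gives folds of knockout over wild type of 2.03 and 0.726 for these isoforms and of 0.565 for Esrra. The untargeted paralog Esrrb rose from 13 ± 0.509 to 29.1 ± 1.72 CPM, with an adjusted p of 4.62e-08 by edgeR. Nkx2-5, the cardiac transcription factor whose promoter drives Cre, fell from 69.1 ± 4.40 to 53.7 ± 3.95 CPM, with an adjusted p of 0.000445 by edgeR. Its call was lost with the level of Y-linked genes as a covariate. Cre was present in the labelled knockout group alone, so its own effects and those of the deletions share the same libraries.

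**Figure D1:**
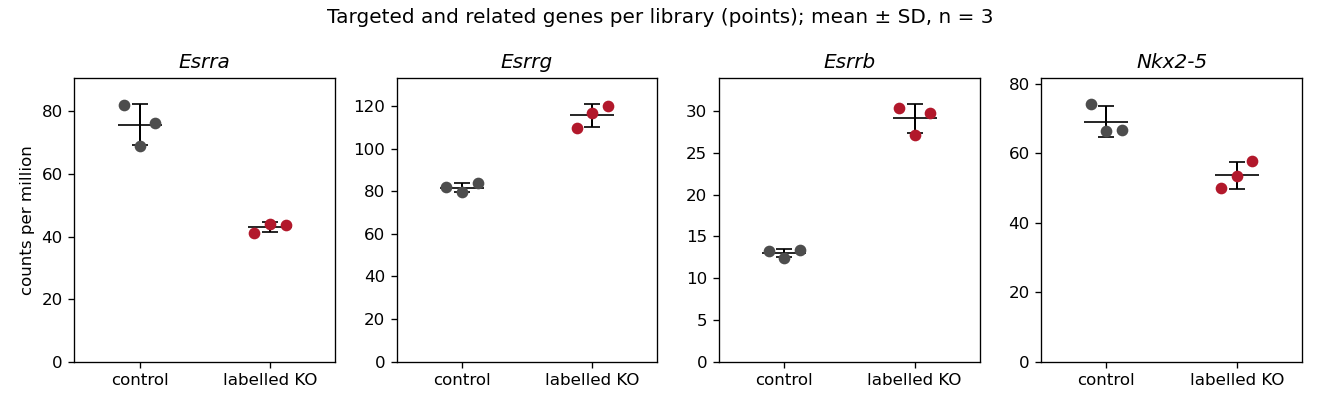
Normalised CPM (vertical axis, from 0) of Esrra, Esrrg, Esrrb and Nkx2-5 in the control and labelled knockout libraries; each point is a library, the horizontal bar is the mean and the whiskers are 1 SD (n = 3 per group). Esrra and Nkx2-5 were lower and Esrrg and Esrrb higher in each labelled knockout library than in each control library.

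The second comparison asked which genes differ in expression between the groups. Of 14292 genes tested, 6349 changed at an adjusted p under 0.05, of which 3198 rose and 3151 fell, and 836 changed at least 2-fold, of which 378 rose and 458 fell. Among the genes with the greatest rises were Fndc3c1, from 0.923 ± 0.259 to 10.3 ± 0.584 CPM, Grin2c, an NMDA receptor subunit, from 0.686 ± 0.254 to 5.87 ± 1.63 CPM, and Ass1, an enzyme of arginine synthesis, from 0.701 ± 0.599 to 6.57 ± 1.29 CPM. Ttyh1 rose 7.92-fold, Gbp6 7.30-fold, Ly86 6.79-fold, 5430419D17Rik 6.67-fold and 9630028I04Rik 6.40-fold. Their control means were low, at 0.748, 2.55, 1.43, 0.669 and 4.23 CPM in that order, so the sizes of these folds are uncertain. Thbs4, a thrombospondin of the extracellular matrix, rose from 29.6 ± 1.81 to 196.4 ± 24.0 CPM. Adjusted p of these 9 genes ran from 9.22e-11 for Thbs4 to 5.85e-06 for Ass1 by edgeR. The log2 fold change of Ass1 went from 3.13 to 4.13 without control replicate 1.

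The deepest fall was that of Ush1c, which encodes the scaffold protein harmonin (mm10 chromosome 7, 46195351 to 46238490). It had 85 to 128 counts in each control library and 0 counts in each labelled knockout library. Against a floor of 3 counts over the labelled knockout group, which covers counting error only, it was at least 152-fold lower. The endocytic adaptor Epn3 fell from 35.8 ± 3.0 to 0.871 ± 0.0638 CPM, a 41.2-fold difference. Wdr72 fell 24.5-fold, the Rab7 effector gene Rilp 12.4-fold, Fndc5, the irisin precursor gene, 11.3-fold and the AMP deaminase Ampd3 10.7-fold. Phf24 fell 8.68-fold, Ybx2 8.38-fold and Tmem35a 7.82-fold. Adjusted p of these 9 genes ran from 2.17e-11 for Epn3 to 1.02e-08 for Ush1c by edgeR. Spp1, which encodes osteopontin, varied among controls (18.95, 2.20 and 6.14 CPM) against 0.659 to 1.01 CPM in the labelled knockouts. Its log2 fold change of -3.56 went to -2.44 without control replicate 1, and its call was lost with robust dispersion (adjusted p 0.0615 by edgeR) and with the Y-linked covariate described below (0.475).

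Sex-linked transcripts differed between the pools. Summed CPM of the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y relative to the raw library total was 0.057, 112.2 and 0.167 in the controls and 323.9, 145.6 and 167.0 in the labelled knockouts. Xist, which is expressed from the inactive X chromosome, stood on the same scale at 2352, 1170 and 2372 CPM in the controls and at 0.949, 1190 and 1263 CPM in the labelled knockouts. Ddx3y was among the 10 greatest rises, at 13.5 ± 23.4 against 81.3 ± 36.4 TMM-scaled CPM, with an adjusted p of 0.0117 by edgeR. That call was lost with DESeq2 (0.490), robust dispersion (0.181) and the Y-linked covariate (0.430). Its log2 fold change of 2.83 went to 11.2 without control replicate 2, and to 2.16 without control replicate 1 or control replicate 3. With Y-linked level as a covariate 3452 genes changed (1700 rose, 1752 fell), and 3644 did (1787 rose, 1857 fell) without the 3 libraries that held near 0 of either the Y-linked genes or Xist (control replicates 1 and 3 and knockout replicate 1), named the libraries of 1 sex here. That leaves 1 control library, which is then assumed to vary like the labelled knockouts. Both settings were chosen after seeing the data. The Y-linked level was higher in each labelled knockout than in each control, so the covariate follows genotype in part. Calls lost with it cannot be laid to sex rather than to lost power.

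Genes of mitochondrial energy conversion fell together. Subunits of respiratory complex I fell in 35 of 36 cases, with a median log2 fold change of -0.99, and all 14 subunits of complexes II and III fell, with a median of -1.46. All 14 subunits of complex IV fell (median -1.31), as did all 17 genes of ATP synthase (median -1.10). Ndufs1, the largest subunit of complex I, fell from 527.6 ± 8.72 to 185.4 ± 10.8 CPM and Ndufv2 from 237.8 ± 1.03 to 101.9 ± 3.49 CPM. Uqcrc2, a core protein of complex III, fell from 563.2 ± 10.7 to 206.4 ± 5.17 CPM, Cox7a2 of complex IV from 261.4 ± 3.65 to 104.4 ± 3.64 CPM, and Atp5g1, of the membrane ring of ATP synthase, from 407.4 ± 24.3 to 129.0 ± 4.95 CPM. Adjusted over the list alone, the counts of lower genes were 35, 14, 14 and 17. By camera with a preset inter-gene correlation of 0.01 the adjusted p of these lists were 1.12e-20, 5.51e-13, 5.80e-12 and 5.00e-13. None of these calls held with an estimated correlation, where camera gave adjusted p of 0.231, 0.225, 0.251 and 0.225. By fry, which tests each list on its own and not against other genes, the adjusted p were 0.000101, 7.96e-05, 9.41e-05 and 7.96e-05. Transcripts of the mitochondrial chromosome were not analysed here.

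Fuel oxidation genes fell as well. All 21 genes of the tricarboxylic acid cycle and pyruvate dehydrogenase fell (median log2 fold change -1.31), all 22 of fatty acid oxidation fell (median -1.17), and 17 of 18 of branched-chain amino acid and ketone oxidation fell (median -0.76). Idh3b, a subunit of isocitrate dehydrogenase, fell from 264.8 ± 2.30 to 77.6 ± 3.07 CPM and Dlst from 351.5 ± 10.2 to 131.1 ± 2.63 CPM. Acsl1, which activates long-chain fatty acids, fell from 327.2 ± 29.9 to 68.3 ± 3.22 CPM, and Acat1, of ketone body use, from 310.2 ± 10.9 to 140.1 ± 3.79 CPM. The counts adjusted over the list alone were 21, 22 and 17 lower genes. Adjusted p by camera were 2.64e-17, 7.30e-15 and 3.33e-09 with the preset correlation. The adjusted p was 0.225 for each of the 3 lists with an estimated correlation. By fry the adjusted p were 7.96e-05, 7.96e-05 and 9.24e-05.

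Uptake and storage of lipids was mixed: 8 of 16 genes fell and 2 rose. Fabp3, a fatty acid binding protein, fell from 572.6 ± 38.5 to 182.6 ± 22.6 CPM and the fatty acid transporter Slc27a1 fell 2.48-fold, while Plin4, which coats lipid droplets, rose from 51.6 ± 11.95 to 87.5 ± 12.6 CPM. The call of Plin4 was lost with robust dispersion (adjusted p 0.0524 by edgeR). That of the other riser, Plin2, at 0.15 on the log2 scale, was lost without control replicate 1 (0.206) or 2 (0.103) or knockout replicate 2 (0.0849) or 3 (0.153), by DESeq2 (0.129), with its size factors (0.0516), with no filter on low counts (0.0513) and in the 3 alternatives chosen after seeing the data (0.0819 to 0.153). Adjusted over the list alone, 12 were lower and 2 higher. The adjusted p by camera was 0.00568 with the preset correlation and adjusted p = 0.401 with an estimated correlation. Without the 3 libraries of 1 sex it was 0.0673, and 0.0783 with the Y-linked covariate. In glycolysis 9 of 20 genes fell and 3 rose, with 10 and 3 adjusted over the list alone. Ldhb, a lactate dehydrogenase subunit, fell from 441.2 ± 35.1 to 127.1 ± 3.25 CPM and hexokinase Hk1 from 385.3 ± 16.6 to 228.2 ± 22.5 CPM. The glucose transporter Slc2a1 rose from 133.9 ± 11.04 to 201.8 ± 19.9 CPM and Hk2 from 179.1 ± 16.2 to 247.4 ± 10.9 CPM. The glycolysis list did not pass, with an adjusted p of 0.0733 by camera, but did without control replicate 2 (0.0197), with no filter on low counts (0.03985) and by fry (0.0186).

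Mitochondrial upkeep genes fell too. Of 76 mitochondrial ribosomal proteins 65 fell, among them Mrps35, from 39.9 ± 1.77 to 17.8 ± 0.304 CPM, and Mrpl42, from 117.4 ± 3.06 to 57.7 ± 4.81 CPM, while none rose. With Y-linked level as a covariate 42 fell. Of 23 genes of mitochondrial biogenesis and dynamics 16 fell and 2 rose. The fusion gene Mfn1 fell from 163.8 ± 6.72 to 57.8 ± 0.291 CPM and Immt, which shapes cristae, from 407.5 ± 10.3 to 194.7 ± 5.52 CPM. Ppargc1a, a coactivator of the estrogen-related receptors, rose from 286.3 ± 27.0 to 433.6 ± 27.7 CPM. Of 13 genes of high-energy phosphate transfer 12 fell and 1, Ak4, rose. The mitochondrial creatine kinase Ckmt2 fell 7.79-fold, from 76.0 ± 6.87 CPM. Adjusted over the list alone, 67, 17 and 12 were lower and 0, 3 and 1 higher. Adjusted p by camera were 2.64e-17, 3.58e-06 and 1.37e-06 with the preset correlation. They were adjusted p = 0.225, 0.225 and 0.257 with an estimated correlation. By fry the adjusted p were 0.000404, 9.24e-05 and 0.000175.

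Of 75 cytosolic ribosomal proteins 49 rose, 1 of them at least 2-fold, and 1, Rpl36, fell, with a median log2 fold change of 0.14. Rpl10 rose from 537.4 ± 13.7 to 667.3 ± 11.4 CPM and Rps18 from 289.8 ± 12.4 to 352.1 ± 12.8 CPM. Reads of such genes can be shared with processed pseudogenes, so single values are uncertain. The counts were 53 higher and 1 lower adjusted over the list alone. The adjusted p by camera was 3.19e-07 with the preset correlation and adjusted p = 0.401 with an estimated correlation. With GC and length trends removed 68 rose and none fell, with a median of 0.27, and Rpl36 stood at 0.0388 on the log2 scale (adjusted p 0.463 by edgeR). With Y-linked level as a covariate 32 rose, and the call of Rpl36 was lost (adjusted p 0.173 by edgeR).

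In the sarcomere, calcium handling and channel lists more genes fell than rose. Of 26 sarcomere genes 15 fell and 3 rose. Tnni3, cardiac troponin I, fell from 1075 ± 48.9 to 302.8 ± 26.1 CPM and the ventricular light chain Myl2 from 5582 ± 130.2 to 2901 ± 298.0 CPM. Pdlim5 rose from 606.4 ± 23.2 to 790.1 ± 37.0 CPM. In calcium handling 10 of 25 fell and 1, Trdn, rose. The T-type calcium channel Cacna1h fell from 89.7 ± 5.61 to 15.1 ± 1.62 CPM, S100a1 from 80.0 ± 6.01 to 33.8 ± 2.80 CPM and the sarcoplasmic calcium pump Atp2a2 1.45-fold, to 1916 ± 41.6 CPM. Of 29 channels and connexins 18 fell and 6 rose. The potassium channel Kcnq1 fell from 82.4 ± 3.29 to 43.0 ± 1.35 CPM, while the potassium channel Kcnj12 rose from 23.7 ± 2.57 to 46.5 ± 1.97 CPM. Adjusted over the list alone, 16, 10 and 18 were lower and 4, 1 and 6 higher. Adjusted p by camera were 0.00331, 0.0266 and 0.00811 with the preset correlation. They were adjusted p = 0.523, 0.257 and 0.300 with an estimated correlation. Without the 3 libraries of 1 sex they were 0.0505, 0.0673 and 0.0505, and the first and second were 0.0774 and 0.0783 with the Y-linked covariate. The rises in calcium handling numbered 3 without knockout replicate 1 and 2 without control replicate 2 or 3, without knockout replicate 2 and in both sex settings, and 5 sarcomere genes rose with GC and length trends removed.

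Fetal and stress-associated cardiac genes rose in 10 of 15 cases and fell in 4, with a median log2 fold change of 0.65. The smooth muscle actin Acta2, expressed in immature cardiomyocytes, rose from 837.0 ± 29.6 to 2741 ± 83.6 CPM. Nppa, which encodes atrial natriuretic peptide, rose from 278.7 ± 22.4 to 1706 ± 312.5 CPM, the atrial light chain Myl7 from 184.1 ± 24.3 to 653.9 ± 39.8 CPM and Ankrd1 from 578.1 ± 100.2 to 1614 ± 194.3 CPM. Myh7b fell from 255.7 ± 20.5 to 87.1 ± 4.92 CPM and Tnni1, slow skeletal troponin I, from 1711 ± 88.7 to 1143 ± 96.3 CPM. Adjusted over the list alone, 11 were higher and 4 lower. The adjusted p by camera was 0.00934 with the preset correlation and adjusted p = 0.225 with an estimated correlation. It was 0.230 with members of other lists left out, among them Nppa, Myl7, Myl4 and Acta1. Of 12 atrial genes 5 rose and 1 fell, the same count as adjusted over the list alone. Bmp10, a growth factor of the atria and trabeculae, rose from 34.3 ± 2.86 to 99.7 ± 12.8 CPM. The atrial list had an adjusted p of 0.0461 by camera with the preset correlation and adjusted p = 0.436 with an estimated correlation. None of its genes fell without control replicate 1, 2 or 3 or knockout replicate 2 or 3, and 2 did without knockout replicate 1. The list did not pass with members of other lists left out (0.800), with the Y-linked covariate (0.322), without the 3 libraries of 1 sex (0.273), without control replicate 1 (0.0991) or knockout replicate 1 (0.152), or with counts thinned to the smallest library (0.0785).

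Of 20 cardiac transcription factors 12 fell, none of them 2-fold, and 1, Tbx20, rose. Prox1 fell from 96.0 ± 5.59 to 76.8 ± 2.496 CPM and Hey2, of the ventricular compact layer, from 163.1 ± 9.995 to 132.8 ± 3.22 CPM. The counts adjusted over the list alone were the same, and the adjusted p by camera was 0.0116 with the preset correlation and adjusted p = 0.225 with an estimated correlation. With Y-linked level as a covariate 6 fell, 2 rose without knockout replicate 2, and the call of Prox1 was lost without the 3 libraries of 1 sex (adjusted p 0.0514 by edgeR).

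Cell type markers moved in different ways. Of 30 fibroblast and matrix genes 25 rose and 1, Pdgfrb, fell, also adjusted over the list alone, with a median log2 fold change of 0.50. Pdgfra, a receptor of cardiac fibroblasts, rose from 109.1 ± 3.28 to 169.8 ± 9.16 CPM and the growth factor Tgfb2 from 50.0 ± 0.472 to 83.7 ± 6.51 CPM. The adjusted p by camera was 3.69e-08 with the preset correlation and adjusted p = 0.257 with an estimated correlation. Of 12 epicardial genes 6 rose and none fell, also adjusted over the list alone, and 1 fell without control replicate 2. Those with the smallest adjusted p were the keratins Krt19, from 8.14 ± 0.222 to 21.4 ± 1.19 CPM, and Krt8, from 3.39 ± 0.385 to 12.1 ± 0.362 CPM, which epithelia express more widely. The adjusted p by camera was 0.00187 with the preset correlation and adjusted p = 0.253 with an estimated correlation. Of 20 endothelial genes 9 rose and 10 fell, or 9 and 11 adjusted over the list alone. Kdr, a receptor of vascular endothelial growth factor, fell from 215.2 ± 8.55 to 152.8 ± 5.56 CPM, while the endocardial gene Npr3 rose from 149.7 ± 3.36 to 269.4 ± 19.6 CPM. That list did not pass (adjusted p 0.773 by camera), and its mean log2 fold change was 0.01 and its median -0.15, with the direction lower in the test.

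**Figure D2:**
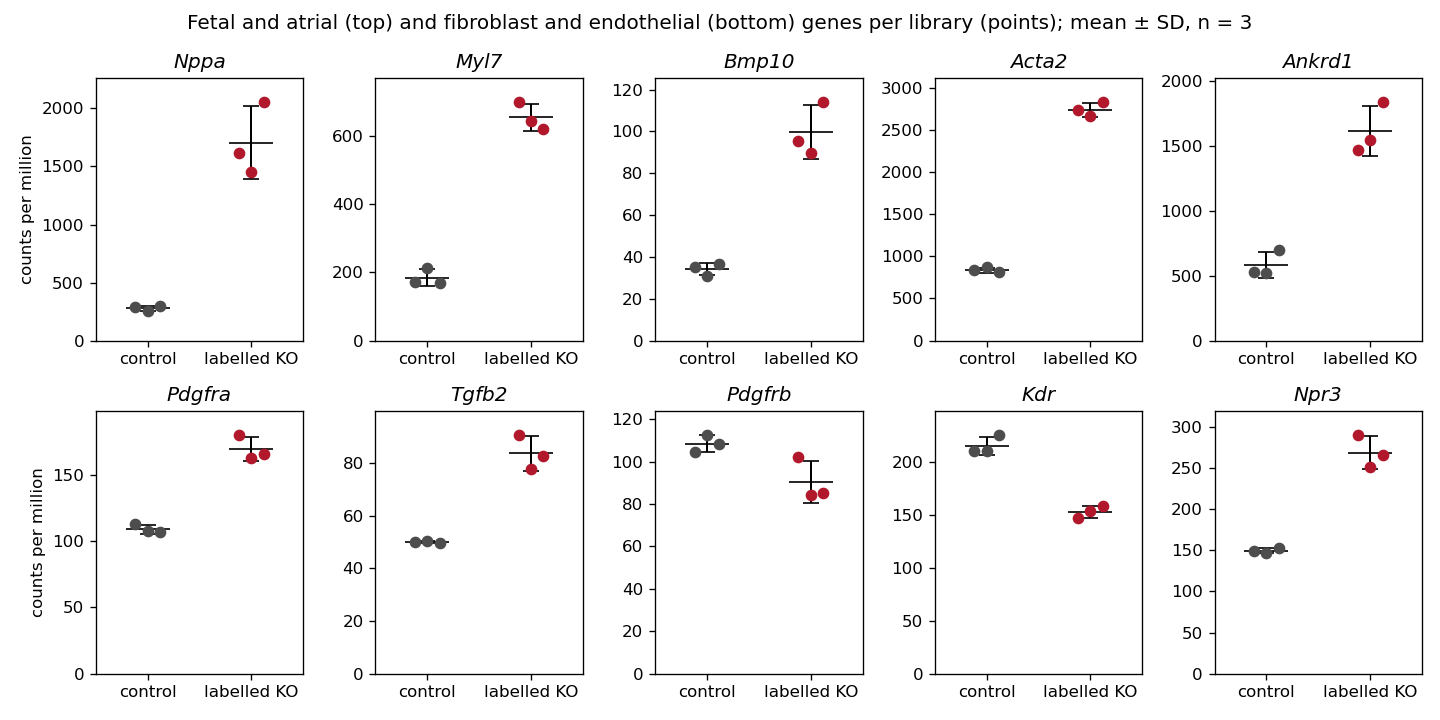
Normalised CPM (vertical axes, from 0) per library of Nppa, Myl7, Bmp10, Acta2 and Ankrd1 in the top row and of the fibroblast list genes Pdgfra, Tgfb2 and Pdgfrb and the endothelial list genes Kdr and Npr3 in the bottom row; points are libraries, horizontal bars means and whiskers 1 SD (n = 3 per group). Pdgfrb and Kdr were lower, and the other genes higher, in each labelled knockout library than in each control library.

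The other lists did not pass by camera. Smooth muscle and pericyte genes rose in 2 and fell in 3 of 10 cases (adjusted p 0.648), with Rgs5 falling from 149.7 ± 7.11 to 76.7 ± 4.11 CPM and Cnn1 rising from 55.8 ± 7.30 to 134.8 ± 1.93 CPM; the median log2 fold change was 0.01, the mean -0.12 and the test direction lower. Macrophage and leukocyte genes rose in 4 and fell in 2 of 16 cases (adjusted p 0.230), among them Csf1r, which rose from 18.4 ± 2.01 to 26.9 ± 0.857 CPM; 3 rose and 1 fell without control replicate 2 or 3 or knockout replicate 3, and 1 and 1 with the Y-linked covariate. Of 13 erythroid genes 1, the transferrin receptor Tfrc, fell, from 243.8 ± 24.5 to 115.2 ± 5.80 CPM, and none rose (adjusted p 0.887); the median was 0.18, the mean 0.10 and the test direction lower, and 4 fell without knockout replicate 2 and 2 rose without knockout replicate 3. Neural and Schwann genes rose in 3 and fell in 2 of 8 cases (adjusted p 0.349), with Uchl1 rising from 33.4 ± 2.06 to 48.1 ± 2.93 CPM. The falls, of Stmn2 and Gap43, did not pass without control replicate 2 (adjusted p 0.0516 and 0.179) or by DESeq2 (0.0891 and 0.106), and 1 gene fell without control replicate 1 or knockout replicate 2 or 3. Among the rises, that of Tubb3 did not pass without control replicate 1 (adjusted p 0.116 by edgeR) or 2 (0.0898). Its call was also lost without knockout replicate 1 (0.171), by DESeq2 (0.16), with thinned counts (0.0534) and with the Y-linked covariate (0.579). Of 7 genes of neighbouring tissues 4, all listed for skeletal muscle, rose and none fell (adjusted p 0.0699), with Acta1, skeletal actin, going from 47.9 ± 5.27 to 93.7 ± 7.48 CPM. Acta1 was also a member of the fetal and stress-associated cardiac list, so its rise does not by itself point to skeletal muscle. The liver genes Alb and Afp of the neighbouring tissue list, which the filter on low counts left out, had 963 and 704 counts in control replicate 3 and at most 26 and 21 in each other library. With no filter 4 genes of the list rose and 3 fell, with a mean of at least 50 counts 2 and 2 of 4, by DESeq2 4 and 1, and without control replicate 1 or 2 or knockout replicate 3 it was 4 and 2. The list passed without control replicate 3 (0.0140), without the 3 libraries of 1 sex (0.0214) and by fry (0.00287). The counts of these 5 lists were the same adjusted over the list alone.

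Of 30 cell cycle genes 11 fell and 1 rose, or 10 and 1 adjusted over the list alone (adjusted p 0.0725 by camera), with Rrm2 falling from 111.9 ± 5.89 to 74.8 ± 4.08 CPM. The lower genes numbered 6 without control replicate 2, 6 without knockout replicate 1, 7 without knockout replicate 3 and 3 with the Y-linked covariate. Ccne1, the 1 that rose, lost its call without control replicate 1 (adjusted p 0.124 by edgeR) or 3 (0.0951). The same held without knockout replicate 1 (0.0892) or 3 (0.117), by DESeq2 (0.167), with the Y-linked covariate (0.4715) and with thinned counts (0.0904). The list passed without control replicate 1 (0.0207) or 3 (0.0268), knockout replicate 2 (0.0316) or the 3 libraries of 1 sex (0.00412), with no filter on low counts (0.0342) and with GC and length trends removed (0.0373). Targets of ATF4 rose in 6 and fell in 8 of 28 cases, also adjusted over the list alone (adjusted p 0.853), with Gars falling from 149.1 ± 5.01 to 88.9 ± 3.80 CPM and Psat1, of serine synthesis, rising from 54.3 ± 2.69 to 82.7 ± 4.95 CPM; the median was -0.03, the mean 0.05 and the test direction lower. Hypoxia-response genes rose in 9 and fell in 9 of 24 cases, or 9 and 10 adjusted over the list alone (adjusted p 0.648), with Hif1a rising from 332.0 ± 2.03 to 590.1 ± 21.6 CPM and Ddit4 falling from 20.1 ± 2.24 to 12.8 ± 0.715 CPM; the median was -0.01, the mean 0.09 and the test direction higher. Antioxidant genes rose in 3 and fell in 10 of 21 cases, also adjusted over the list alone (adjusted p 0.105, or 0.00041 by fry). With the Y-linked covariate 4 ATF4 targets, 4 hypoxia-response genes and 6 antioxidant genes fell. Sod2, the mitochondrial superoxide dismutase, fell from 335.7 ± 4.42 to 101.3 ± 8.38 CPM and Nqo1 rose from 7.66 ± 0.874 to 18.7 ± 2.94 CPM.

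**Figure D3:**
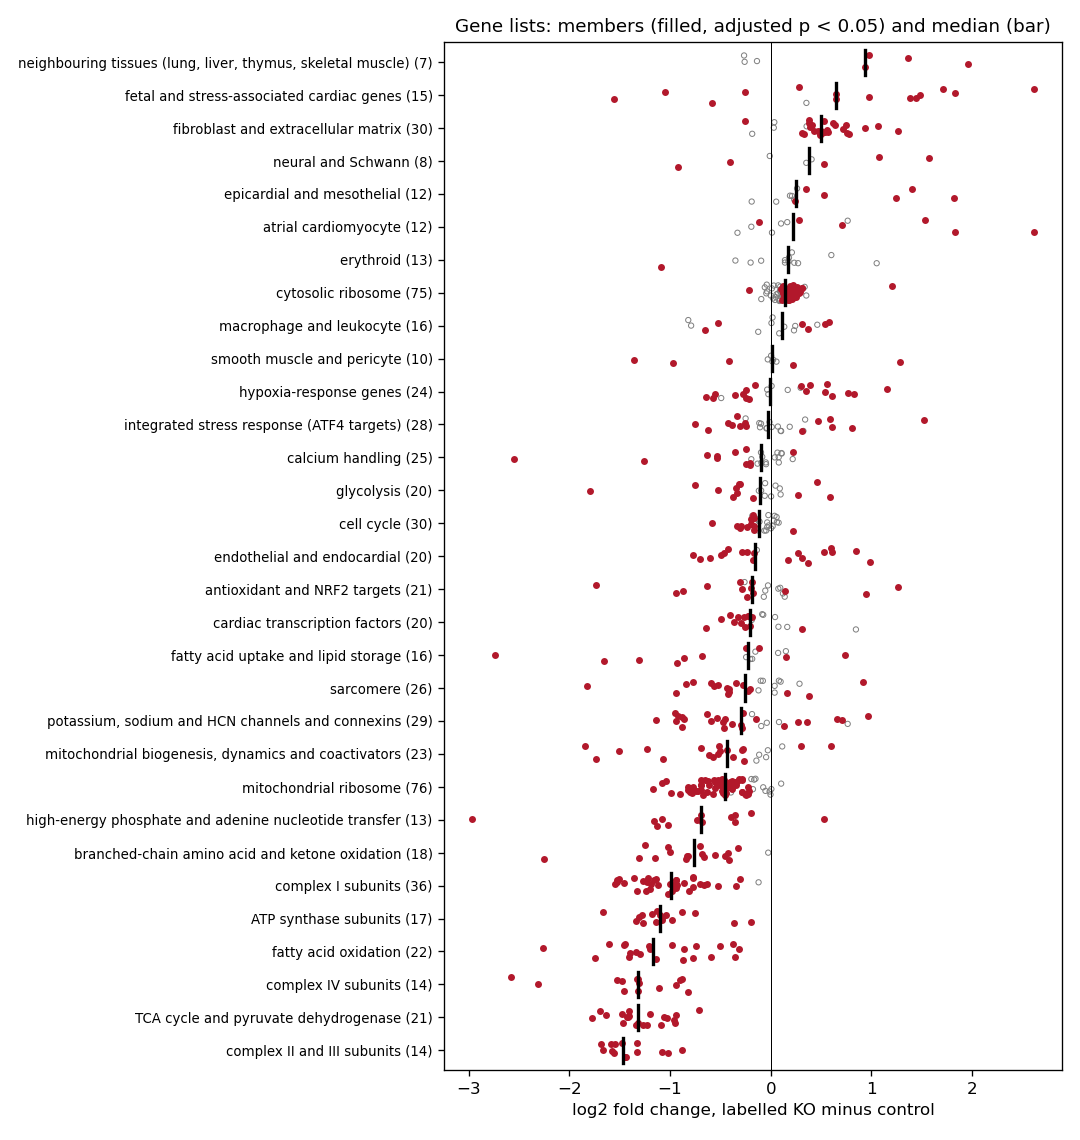
Log2 fold change, labelled knockout minus control (horizontal axis), of each tested member of 31 gene lists (vertical axis, with the number of members tested in parentheses); filled points passed an adjusted p of 0.05 by edgeR, open points did not, and black bars are list medians. Complexes II and III had the lowest median, at -1.46, and neighbouring tissues the highest, at 0.93 over 7 tested members. Fibroblast and matrix genes had a median of 0.50.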

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

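Of the tests in this part, only that of other groupings of the gene list calls was fixed before its result was seen. The mapping sheet, outside the main measurement, gives shares of reads that sum to a whole, so that a fall in one raises others. Reads between genes made up 19.8% ± 3.07 in the labelled knockouts against 24.9% ± 2.0 in the controls (SD, n = 3), a difference of -5.12 percentage points (exact permutation p = 0.1, the smallest this design allows). Reads within introns made up 40.3% ± 1.62 against 37.9% ± 1.16, which is 2.37 percentage points more (exact permutation p = 0.1). Reads fully inside exons made up 39.2% ± 1.53 against 36.4% ± 0.818, which is 2.73 percentage points more (exact permutation p = 0.1).

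Of the 10 splits of the 6 libraries into 3 and 3, only 1, the real one, gave as many changed genes (6349, highest other 0) or as many changed at least 2-fold (836, highest other 0) by edgeR; at an unadjusted p under 0.05 the real split gave 7355 genes and the others 94 to 260. For gene lists called by camera with the preset correlation, 2 of the 10 splits gave at least 20 calls. They were the real one, with 20, and 1 other, with 22. The mixed splits gave 8 to 22 called lists, so such calls also arise in groupings that mix controls and labelled knockouts. Splits of 3 against 3 are too few for a share under 0.05. Each other split also puts controls and labelled knockouts in the same group, so their difference counts as spread within groups. That by itself lowers the number of changed genes in those splits, so they do not measure chance.

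Esrrg reads were higher in the libraries labelled knockout. Exchanged labels of the groups are argued against by Esrra, with a log2 fold change of -0.83. Transcription from outside the deleted part of the gene may account for the rise. It cannot be told apart from other changes at the locus, because counts per exon are not at hand and the isoform NM_001243792 went by -0.46.

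Nppa, Myl7 and Bmp10 were higher in the libraries labelled knockout. For atrial tissue in the pools, the other 7 atrial genes with a lower control level than Myl7 were examined. Their median log2 fold change was 0.10 (SD 0.418) against 1.54 for Bmp10. These values cannot decide it, because a rise from atrial tissue depends on each gene's excess in atria over ventricles. That excess was not measured here. A stress-associated programme in the labelled knockout ventricles may account for the rises. Of the other called fetal and stress-associated genes 8 rose and 4 fell (exact two-sided sign test over genes, which are not independent, p = 0.388), so this stays open.

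Fibroblast and matrix genes were higher in the libraries labelled knockout. A lower share of cardiomyocytes as the only change would raise endothelial genes as well. Their median lay 0.65 below the fibroblast median on the log2 scale (permutation p = 0.00044 over genes, which are not independent), more than the endothelial SD of 0.53. The fibroblast list was examined because it had been seen to rise, so this p-value is no independent support. The gap argues against that single change. A lower share beside other changes stays open, because endothelial genes can change on their own. Of 26 sarcomere genes 15 fell and 3 rose, and a lower share would lower them. Endothelial genes went both ways (9 rose, 10 fell), 6 of 12 epicardial genes rose, and with the Y-linked covariate the fibroblast and endothelial medians were 0.33 and -0.14. In the main fit the medians of the smooth muscle, leukocyte and epicardial lists were 0.01, 0.11 and 0.25. Scaling stays open, because the other scalings moved the list's median log2 fold change by at most 0.005. More fibroblasts could account for the rise and cannot be told apart from higher expression per cell, since members rose unevenly, with an SD of 0.32 on the log2 scale.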

How the results depend on the processing

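Over the alternatives run, 3258 of 3260 values of 172 named genes kept their direction and 3177 also their side of the threshold; 47 calls were lost in alternatives set before the data were examined and 34 in those chosen after seeing the data. The reversal was that of Rpl36, at 0.0388 on the log2 scale with GC and length trends removed, with or without the replicate block, and the cause was not tested. Changed genes were 5320 to 6113 with a library left out and 5150 by DESeq2. Replicate numbers do not pair the samples (deviation correlations -0.01, -0.02 and 0.10 for the shared numbers), and the replicate block gave 6412 changed genes; with it 1 erythroid gene rose and the cell cycle list passed by camera (adjusted p 0.0358, or 0.0142 with GC and length trends also removed, where 4 erythroid and 3 calcium handling genes rose). Both sex settings lowered the count by over 1.5 times: 3452 genes (1700 rose, 1752 fell) with the Y-linked covariate and 3644 (1787 rose, 1857 fell) without the 3 libraries of 1 sex, which has fewer samples. With an estimated correlation 0 of 31 lists were called by camera, against 20 with the preset one and 23 by fry; 4 lists had an unadjusted p under 0.05 with the estimated one. Of 360 other values of called lists 14 lost the call and 0 reversed. Lists that were not called changed direction, with these camera p. ATF4 targets went higher with GC and length trends removed (0.929, or 0.784 with the replicate block), with the Y-linked covariate (0.769) and without the 3 libraries of 1 sex (0.639). Smooth muscle went higher with a mean of at least 50 counts (0.975). Erythroid genes went higher with the replicate block (0.816), with trends removed (0.956, or 0.601 with the block), with the Y-linked covariate (0.671) and without the 3 libraries of 1 sex (0.836). Leaving out 1 library, p signed by direction ran from -0.82 to 0.97 for ATF4 targets, from -0.76 to 0.99 for endothelial genes and from -0.83 to 0.92 for erythroid genes; the causes were not tested. In simulated counts, with far fewer changed genes than the data, 44.9% of changes of the smallest fold tried were recovered. Small changes can be missed in the data too, but by what share is not known.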

Other observations

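Further mitochondrial gene groups, in lists written after the data were seen, fell with the respiratory subunits. All 7 genes of the malate-aspartate shuttle, which moves reducing equivalents into mitochondria, fell, with Got1 going from 245.6 ± 13.6 to 62.3 ± 4.50 CPM and Got2 from 443.2 ± 17.5 to 144.1 ± 5.45 CPM (SD, n = 3). Of 13 genes of coenzyme Q synthesis 10 fell, among them Coq9, from 127.0 ± 5.97 to 52.9 ± 0.605 CPM, and Coq8a, from 73.9 ± 6.38 to 19.3 ± 2.95 CPM. Assembly factors fell in 14 of 15 cases for complex I, such as Foxred1, from 77.1 ± 2.77 to 30.8 ± 0.790 CPM, and in 14 of 19 cases for complex IV, such as Lrpprc, from 284.3 ± 8.75 to 143.0 ± 4.56 CPM. Mitochondrial aminoacyl-tRNA synthetases fell in 14 of 17 cases and protein import genes in 20 of 28, with Hspa9 going from 659.7 ± 13.2 to 333.2 ± 9.33 CPM. Of 16 peroxisome biogenesis genes 4 fell and 1 rose. Some of these genes were already counted above. Mdh1 and Mdh2 of the shuttle were in the tricarboxylic acid cycle list, and Timm44, Tomm20 and Tomm40 of protein import in the biogenesis list. With an estimated correlation camera called 0 of the 10 added lists, at adjusted p from 0.0675 to 0.411, against 8 with the preset correlation, 1 of which is a list of keratins already seen to rise; 4 had an unadjusted p under 0.05 with the estimated one.

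Skeletal muscle contractile isoforms rose in 9 of 12 cases and none fell; Myh3 and Myh8 among them had been seen to rise before this list was written. Myl1, a fast skeletal and embryonic light chain, rose from 31.2 ± 0.684 to 126.9 ± 6.54 CPM. The embryonic myosin Myh3 rose from 1.30 ± 0.179 to 3.26 ± 0.446 CPM, a call lost without the 3 libraries of 1 sex, as was that of Myh8, and Mybpc1 2.10-fold, both at low levels beside Myl1.

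Gm20594 held 1.31% ± 0.0704 of gene counts in controls and 0.824% ± 0.0310 in labelled knockouts (SD, n = 3). Its reference transcript matched the mitochondrial gene mt-Rnr2 over 439 bases at 88.4% identity.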
